A study of Homo sapiens with 27 samples.

How the data were processed

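RNA from the EPI-200 model, a layered epidermis grown from human keratinocytes, was measured on 27 one-colour microarrays, with 3 arrays in each of 9 groups (control, 10 cGy and 2.5 Gy of 4.5 MeV protons, each at 4, 16 and 24 h). Groups, doses and times were taken from the labels, and no sample was left out. The labels state 100 ng of RNA per labelling and 3 biological repeats per condition. Replicate numbers serve as names only, because nothing in the labels pairs the cultures that share one.

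Per the file headers, the arrays were an Agilent whole human genome design with 4 arrays per slide, and the scanner files were extracted by Agilent Feature Extraction, given as version 9.1 in the submitters' processing notes. The deposited scanner files give each spot an intensity after background subtraction and detrending within its array, with no scaling between arrays, so values can be negative. Per the file headers, the files also hold the intensity of the spot's pixels and of its local background, and other columns that state whether a spot lay well above background, was saturated or was uneven. The deposited value table of the series holds log2 values of the same signal plus a constant per array, with blanks where a spot was not well above background or otherwise marked, and it was used only as an alternative.

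Each background-subtracted intensity was divided by the 75th percentile of its array, held at 0.02 of that percentile where it was lower, and put on the log2 scale. A held value marks the floor, so a fold against a group of dim spots is a lower bound and is printed as "at least". Of 41000 gene probes, 27609 were given a gene symbol from the reference: 23675 by RefSeq accession, 2805 by symbol and 1129 by synonym. The other 13391 kept their probe or transcript name and were tested without a symbol. Another 75 probes were left out because they measure genes from which personal traits could be read. A probe entered if its spots lay well above background on at least 3 of the 27 arrays, and a gene with several probes was represented by the one with the highest mean, which gave 26220 genes, 16220 of them with a symbol. Depth on an array means signal over background: between 27566 and 31505 spots lay well above background on 25 arrays, and 39545 and 39588 on the other 2. The number of arrays limits the precision.

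A linear model with 9 group means was fitted across all 27 arrays with limma 3.58.1 in R 4.3.3, so that all groups shared one estimate of spread per gene. Each comparison used limma's moderated test with Benjamini-Hochberg adjustment within the comparison, and a gene was counted as changed at an adjusted p under 0.05. The 12 planned results were both doses against the control of the same time, 2.5 Gy against 10 cGy at each time, F tests of whether the response to each dose differed between times, and an F test of time in the controls. Gene lists (27) were written before the data were examined, and each was tested against all other genes with limma's camera at its preset correlation, adjusted over the lists within a comparison. Camera with a correlation estimated from the residuals and fry, a test of whether a list's genes move on balance one way, were run beside it. The p-values that follow come from limma unless another test is named, and all are two-sided.

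Named genes follow a rule written before the data were examined. For each dose against control it takes the 8 largest rises and 8 largest falls among changed genes with a symbol whose 3 irradiated arrays all lay above or all below the 3 controls. It adds up to 4 members with the smallest p from each list that has a changed member. CDKN1A, MDM2, GDF15, KRT14, KRT10 and IVL were taken whatever their p. For 2.5 Gy against 10 cGy it takes 4 rises and 4 falls, for the F tests the 6 smallest p, and where fewer than 10 genes pass, the 6 genes with the smallest p. The text prints those that describe a group, and the tables hold all.

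Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter, a filter on all 27 arrays, the mean of a gene's probes, a replicate block, slide as a random block, array weights, an intensity trend in the variance prior, an unadjusted p under 0.001, the deposited log2 table, a fit of only the groups compared, and leaving out each array in turn. Chosen after seeing the data were slide as a fixed block, leaving out 2 arrays at 24 h, both together, a floor of 0.01, and holding 56 spots on 9 arrays before normexp because their local background far exceeded their signal. Scan day as a block was not run, since it is fixed by time and parts no dose from its control.

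The test was tried on simulated data, with the means and spreads of the 26220 genes, normal noise and known log2 changes between 2.5 Gy and control at 4 h. Of 50 genes each, it called 4 at a change of 0.5, 28 at 1, 40 at 2 and 47 at 3, all in the right direction, with 8 unchanged genes called. The changed genes were drawn from those with a mean over 2 log2 units above the floor, so recovery of dim genes was not tried. The noise held no slide effect, so calls that come from slides were not tried either. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.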

Results

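The EPI-200 model is a human epidermal tissue grown from keratinocytes at the air surface, with basal, spinous and cornified layers. The series title asks how it responds to a high and a low dose of protons. Tissues received 2.5 Gy or 10 cGy of 4.5 MeV protons or no irradiation, and RNA was taken 4, 16 or 24 h later, with 3 arrays in each of 9 groups. Values are log2 signals relative to the 75th percentile of each array, and differences are log2 fold changes ± SE from limma with n = 3 against 3 unless stated. On 25 arrays 63.6% to 72.6% of spots lay well above background. The other 2 arrays, 10 cGy replicate 2 and 2.5 Gy replicate 1 at 24 h, had 91.3% and 91.2%, and they shared a slide. At each time the 3 controls shared a slide with 10 cGy replicate 1, while 10 cGy replicates 2 and 3 shared another with 2.5 Gy replicates 1 and 2, and 2.5 Gy replicate 3 was alone. A fit with slide as a fixed block therefore compares 10 cGy with control through 1 irradiated array, and 2.5 Gy with control only through the 10 cGy arrays. Its values stand beside the others below. Arrays of 4 h were scanned on 1 day and those of 16 and 24 h on another.

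**Figure D1:**
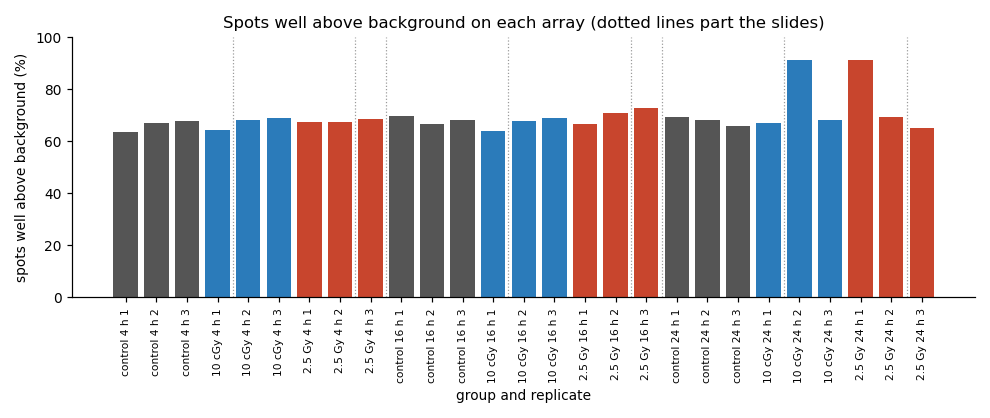
Share of spots well above background (%, vertical axis) on each of the 27 arrays (horizontal axis, group and replicate number, grey for control, blue for 10 cGy, red for 2.5 Gy), with dotted lines between slides. The 2 arrays at 91.2% and 91.3% stand above the other 25, which lie between 63.6% and 72.6%.

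At 4 h after 2.5 Gy, genes of cell division were lower and genes of the p53 response were higher than in the controls. Of 54 measured mitosis and G2/M genes, 25 fell and none rose, 46 fell when adjusted over the list alone, and the list's median was -0.999 (camera adjusted p = 3.8e-50, and 0.002 with an estimated correlation). SPC25 (NCBI gene 57405, chromosome 2), part of the kinetochore, fell by 1.59 ± 0.17 (adjusted p = 8.14e-05). DLGAP5, a spindle protein, fell by 1.46 ± 0.19, CCNB2, a mitotic cyclin, by 1.24 ± 0.17, and PLK1, a mitotic kinase, by 1.17 ± 0.18. Among 49 DNA replication and S phase genes 6 fell and 1 rose, with 15 lower and 2 higher when adjusted over the list alone (median -0.447, adjusted p = 0.0281 with an estimated correlation). The helicase subunits MCM2 and MCM6 fell by 0.895 ± 0.174 and 0.919 ± 0.182. In the list of 35 homologous recombination and Fanconi anaemia genes 1 fell, FANCD2 by 0.676 ± 0.154, and 5 when adjusted over the list alone (median -0.371, adjusted p = 0.0337 with an estimated correlation).

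Of 40 measured p53 target genes, 4 rose and none fell at 4 h after 2.5 Gy, 11 rose when adjusted over the list alone, and the median was 0.367 (camera adjusted p = 2.45e-11, and 0.0178 with an estimated correlation). GDF15 (NCBI gene 9518, chromosome 19), a secreted stress cytokine, rose by 2.69 ± 0.28 (adjusted p = 8.14e-05). The death receptor TNFRSF10B rose by 0.659 ± 0.141, the decoy receptor TNFRSF10C by 1.68 ± 0.29, and the cell cycle inhibitor CDKN1A by 0.690 ± 0.164. MDM2, which targets p53 for breakdown, had a value of 0.731 ± 0.248 that did not pass (adjusted p = 0.178). Inflammatory cytokine and NF-kB genes had a median of 0.307 with 3 of 37 raised, 5 when adjusted over the list alone (adjusted p = 0.0281 with an estimated correlation): the prostaglandin synthase PTGS2 rose by 1.75 ± 0.32, the chemokine CXCL1 by 1.33 ± 0.31 and the NF-kB subunit RELB by 1.04 ± 0.23. Among 25 immediate early genes 2 rose, 6 when adjusted over the list alone (median 0.29, adjusted p = 0.0178 with an estimated correlation). These were FOSL1, a member of the AP-1 family, at 1.11 ± 0.17 and KLF2, a transcription factor, at 1.00 ± 0.21. Matrix remodelling and wound response genes had 6 of 42 raised, 8 raised and 2 lowered when adjusted over the list alone (median 0.16, adjusted p = 0.0702 with an estimated correlation), and the median was -0.0119 with slide as a fixed block. Among these the stromelysin MMP3 (NCBI gene 4314, chromosome 11) was at least 9.07-fold higher, as it was not well above background in any control. S100A7A, an antimicrobial protein of activated keratinocytes, was at least 14.9-fold lower and not well above background after irradiation. KRT14, a basal keratin, and KRT10, a spinous keratin, had values of -0.0675 ± 0.132 and -0.176 ± 0.154, and involucrin (IVL) had 0.570 ± 0.186, none of which passed.

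In all, 406 of 26220 genes changed at 4 h after 2.5 Gy, 194 up and 212 down. On 48 of them 1 group was not well above background on any array. Slide as a fixed block gave 256 changed genes, a mitosis median of -1.78 (adjusted p = 3.89e-05 with an estimated correlation) and a p53 median of 0.359 (adjusted p = 0.0997 with an estimated correlation). GDF15, MMP3 and the named mitosis genes still passed there, while CDKN1A at 0.75 (adjusted p = 0.477) did not. Scaled to each array's median, 135 genes changed, of which 21.5% rose in place of 47.8%.

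At 4 h after 10 cGy, MMP3 was at least 24.9-fold higher than in the controls, where it was not well above background. Follistatin (FST), which binds activins, rose by 2.34 ± 0.39, CYP1B1, a cytochrome P450, by 2.17 ± 0.27, and CH25H, which makes a hydroxylated cholesterol, by 2.24 ± 0.28. Matrix remodelling and wound response genes had 6 raised and 1 lowered of 42, with 9 and 4 when adjusted over the list alone (median 0.145, adjusted p = 0.165 with an estimated correlation). SERPINB2, an inhibitor of plasminogen activation, rose by 1.45 ± 0.21 and the plasminogen activator PLAT was at least 4.38-fold higher, while the gelatinase MMP9 fell by 1.55 ± 0.31. Of 25 immediate early genes 3 rose, over all genes and when adjusted over the list alone (median 0.119, adjusted p = 0.165 with an estimated correlation), among them FOSL1 by 1.24 ± 0.17 and KLF2 by 0.941 ± 0.206. PTGS2 and the early response gene IER3 rose by 1.86 ± 0.32 and 0.815 ± 0.191 among 37 inflammatory genes, of which 5 rose when adjusted over the list alone (median 0.223, adjusted p = 0.165 with an estimated correlation). Interferon-stimulated genes had 1 raised and 4 lowered, with MX1 down by 1.82 ± 0.38 and ISG20 up by 0.794 ± 0.167, and the list as a whole did not pass (median -0.018, adjusted p = 0.127).

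Genes of mitosis and G2/M had a median of -0.477 at 4 h after 10 cGy, with 1 of 54 lowered, UBE2C by 0.786 ± 0.188, and 11 when adjusted over the list alone (camera adjusted p = 1.84e-15, but adjusted p = 0.165 with an estimated correlation). The p53 targets had a median of 0.138 and none passed (adjusted p = 0.105). CDKN1A at 0.167 ± 0.164, GDF15 at 0.414 ± 0.282 and MDM2 at 0.196 ± 0.248 did not pass either, nor did KRT14 at 0.139 ± 0.132, KRT10 at 0.0781 ± 0.154 or IVL at 0.299 ± 0.186. The largest falls included S100A7A at -3.19 ± 0.48 and BOC, a hedgehog coreceptor, at -3.20 ± 0.61. In all 307 genes changed, 164 up and 143 down. A fixed block for slide gave 472 changed genes and a mitosis median of -0.933, with 20 genes lowered (adjusted p = 0.000641 with an estimated correlation). The 2 arrays of 10 cGy on the other slide had a mitosis median of -0.258 against the controls. Scaled to each array's median 104 genes changed, of which 25% rose in place of 53.4%.

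Compared directly at 4 h, 2.5 Gy and 10 cGy differed in 2 genes, GDF15 and SPC25. GDF15 was higher after 2.5 Gy by 2.28 ± 0.28 (adjusted p = 0.00272), and SPC25 was lower by -1.07 ± 0.17 (adjusted p = 0.0491). The next smallest p-values belonged to RHOBTB2 (-0.939 ± 0.158, adjusted p = 0.0758), PPAT, an enzyme of purine synthesis (-0.738 ± 0.131, adjusted p = 0.0870), and CDKN3, a phosphatase of the cell cycle (-1.16 ± 0.21, adjusted p = 0.0968), none of which passed. The p53 list was higher after 2.5 Gy with a median of 0.235, and the mitosis list lower with -0.537, each with adjusted p = 0.0342 with an estimated correlation. Adjusted over the list alone, 4 p53 targets were higher and 17 mitosis genes lower. On the slide that held both doses, 2 arrays of each, the mitosis median was -0.751 and 3 of 54 genes were higher after 2.5 Gy. CDKN1A at 0.523 ± 0.164 and MDM2 at 0.535 ± 0.248 did not pass. The doses differed in 29 genes with slide as a fixed block, 34.5% of them higher in place of 50%.

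**Figure D2:**
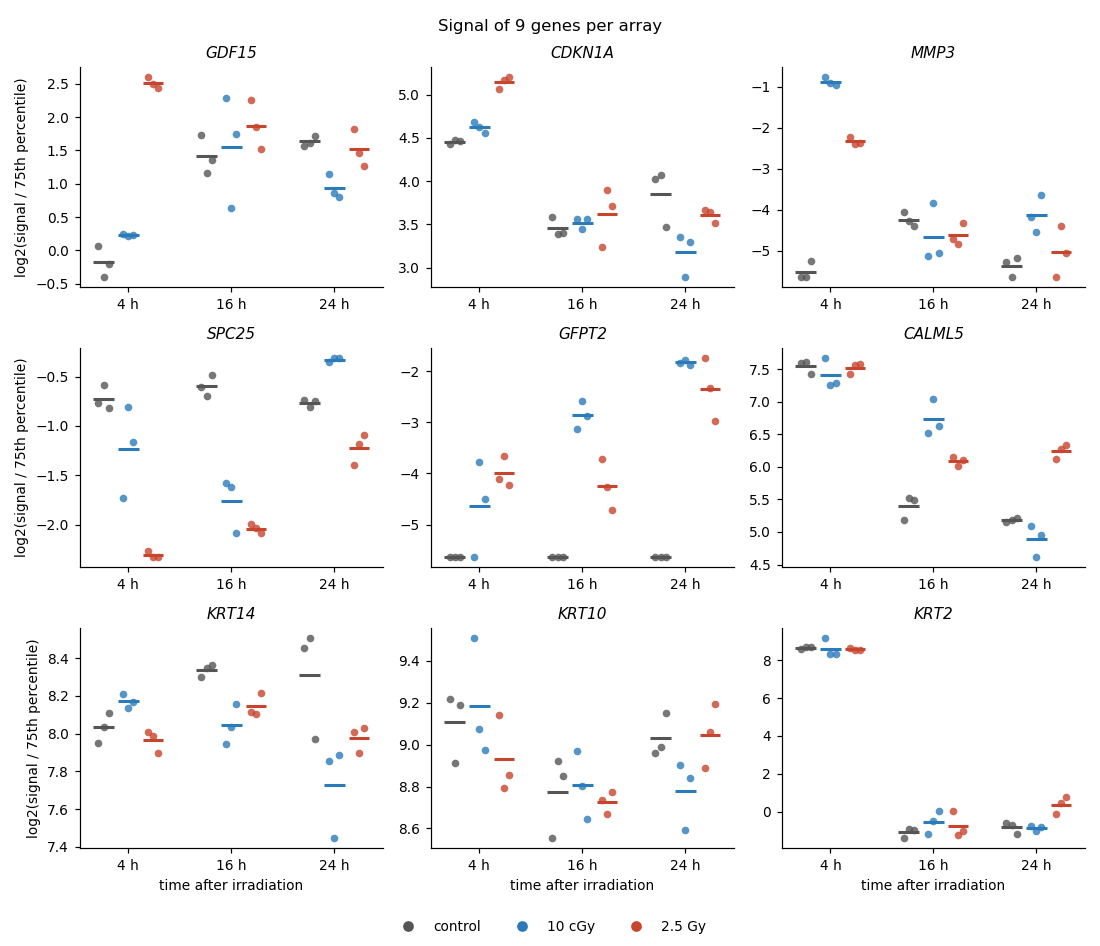
Signal of 9 genes on each array (vertical axis, log2 of signal over the array's 75th percentile) by time after irradiation (horizontal axis), for control (grey), 10 cGy (blue) and 2.5 Gy (red), with bars at the means of 3 arrays. GDF15 and CDKN1A at 4 h lay highest after 2.5 Gy, MMP3 at 4 h lay highest after 10 cGy, and KRT2 was far lower in every group at 16 and 24 h than at 4 h.

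At 16 h after 2.5 Gy, genes of cell division were lower again. Of 54 mitosis and G2/M genes 16 fell and none rose, 36 fell when adjusted over the list alone, and the median was -0.82 (camera adjusted p = 1.16e-32, and 0.0178 with an estimated correlation). SPC25 fell by 1.45 ± 0.17 (adjusted p = 0.000284), PLK1 by 1.27 ± 0.18, DLGAP5 by 1.18 ± 0.19 and CCNB2 by 1.07 ± 0.17. Of 49 replication genes 3 fell, 16 when adjusted over the list alone (median -0.42, adjusted p = 0.0938 with an estimated correlation), with MCM3 down by 1.06 ± 0.18. Of 35 homologous recombination and Fanconi anaemia genes 2 fell, 9 when adjusted over the list alone (median -0.318, adjusted p = 0.0816 with an estimated correlation). Basal keratinocyte genes had 2 of 26 lowered, DST by 0.798 ± 0.154 and the laminin receptor ITGA6 by 0.648 ± 0.146, and 8 when adjusted over the list alone (median -0.274, adjusted p = 0.123 with an estimated correlation). Barrier lipid genes had 2 of 29 raised, 4 when adjusted over the list alone (median 0.224, adjusted p = 0.312 with an estimated correlation). OAS1, an interferon-stimulated enzyme (NCBI gene 4938, chromosome 12), rose by 1.13 ± 0.13, while IFITM1, of the same list, fell by 1.21 ± 0.21.

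The p53 targets as a list did not pass at 16 h after 2.5 Gy (median 0.0301, adjusted p = 0.882), and 2 fell, the DNA polymerase POLH by 0.715 ± 0.130 and TNFRSF10B by 0.613 ± 0.141. GDF15 at 0.454 ± 0.282, CDKN1A at 0.160 ± 0.164, MDM2 at 0.0063 ± 0.248, KRT14 at -0.192 ± 0.132, KRT10 at -0.0501 ± 0.154 and IVL at 0.210 ± 0.186 did not pass. In all 173 genes changed, 40 up and 133 down. When slide was a fixed block 20 genes changed, no mitosis gene was among them, and the mitosis median was -0.468 (adjusted p = 0.116 with an estimated correlation). Without the 2 arrays of 24 h, which enter only through the shared spread, 471 genes changed. The share that rose was 23.1%, 11.3% with scaling to the median and 34.8% with quantile normalization. It was 48.9% with array weights and 55% with slide as a fixed block, so the excess of falls depends on the setting.

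At 16 h after 10 cGy, 27 of 54 division genes and 11 of 26 basal layer genes were lower and 10 of 26 histone genes higher, and none of the lists in this paragraph passed with an estimated correlation. Of 54 mitosis and G2/M genes 27 fell, 34 fell and 1 rose when adjusted over the list alone, and the median was -0.773 (camera adjusted p = 1.16e-20, but adjusted p = 0.0603 with an estimated correlation). CCNB1, the main mitotic cyclin, fell by 1.20 ± 0.17, PLK1 by 1.25 ± 0.18 and SPC25 by 1.16 ± 0.17. Of 26 basal keratinocyte genes 11 fell, 14 when adjusted over the list alone (median -0.556, adjusted p = 0.0856 with an estimated correlation), with DST down by 0.918 ± 0.154 and the hemidesmosome collagen COL17A1 by 0.634 ± 0.123. Of 35 homologous recombination and Fanconi anaemia genes 6 fell, 13 when adjusted over the list alone (median -0.507, adjusted p = 0.0705 with an estimated correlation), with the checkpoint kinase ATR down by 0.777 ± 0.134. Replication-dependent histone genes had 10 of 26 raised, 18 when adjusted over the list alone (median 0.524, adjusted p = 0.0856 with an estimated correlation), with H2AC8 up by 0.952 ± 0.187. Cornified envelope genes had 3 of 47 raised, 4 when adjusted over the list alone (median 0.251, adjusted p = 0.184 with an estimated correlation), with repetin (RPTN) up by 2.12 ± 0.34. Spinous layer genes had 2 of 25 raised in both counts (median 0.271, adjusted p = 0.237 with an estimated correlation), with CALML5 (NCBI gene 51806, chromosome 10), a calcium-binding protein of differentiation, up by 1.33 ± 0.15 (adjusted p = 0.000245).

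Among 25 immediate early genes 5 rose and 1 fell at 16 h after 10 cGy, 9 and 2 when adjusted over the list alone (median 0.26, adjusted p = 0.0603 with an estimated correlation). EGR1 rose by 0.862 ± 0.161 and KLF2 by 1.05 ± 0.21, and MYC, a growth regulator, fell by 0.739 ± 0.154. GFPT2 (NCBI gene 9945, chromosome 5), an enzyme of hexosamine synthesis, was at least 6.88-fold higher and not well above background in the controls. OAS1 rose by 1.42 ± 0.13 (adjusted p = 1.54e-05). The p53 list did not pass (median -0.142, adjusted p = 0.166): SESN2, a stress-induced sestrin, rose by 0.733 ± 0.140 and POLH fell by 1.09 ± 0.13. GDF15 at 0.137 ± 0.282, CDKN1A at 0.0638 ± 0.164, MDM2 at -0.0126 ± 0.248, KRT14 at -0.292 ± 0.132, KRT10 at 0.0299 ± 0.154 and IVL at 0.110 ± 0.186 did not pass. In all 1109 genes changed, 272 up and 837 down. With slide as a fixed block 44 genes changed, the mitosis median was -0.535 (2 lowered, adjusted p = 0.00572 with an estimated correlation), the histone median 0.483 and the basal median -0.358, and CALML5, OAS1 and GFPT2 still passed. Scaled to the median 24 genes changed, and the share that rose was 24.5%, against 34.6% with normexp and 40.6% in the deposited values. With slide as a fixed block it was 54.5%, so the excess of falls did not hold there.

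At 16 h the direct comparison of the doses found 57 genes, 41 higher and 16 lower after 2.5 Gy. KCTD4 was higher by 1.61 ± 0.20 (adjusted p = 0.0028), PLAC1 by 1.34 ± 0.22 and the heat shock cochaperone CHORDC1 by 0.636 ± 0.132. SEMA7A, a membrane-anchored semaphorin, was lower by -1.51 ± 0.26 and the surface antigen PSCA by -1.76 ± 0.32. No histone gene passed over all genes, and 9 of 26 were lower when adjusted over the list alone (median -0.342, camera adjusted p = 1.81e-11, but adjusted p = 0.371 with an estimated correlation). The mitosis list did not differ (median 0.0293, adjusted p = 0.325), and on the shared slide its median was 0.164. Between the doses 139 genes differed with slide as a fixed block. A fit of only the 6 arrays compared gave 0, and so did scaling to the median (1772 and 1493 at an unadjusted p under 0.05). Another split of these arrays into 3 and 3 gave 131. The share higher after 2.5 Gy was 71.9%, against 36.1% with normexp and 42.9% in the deposited values.

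At 24 h after 2.5 Gy, 14 of 54 division and 12 of 49 replication genes were lower and 10 of 47 cornified envelope and 6 of 37 inflammatory genes higher, and none of these lists passed with an estimated correlation. Of 54 mitosis and G2/M genes 14 fell, 21 when adjusted over the list alone (median -0.513, camera adjusted p = 4e-12, but adjusted p = 0.153 with an estimated correlation), with the survivin gene BIRC5 down by 1.06 ± 0.19 and SGO1, which guards centromere cohesion, by 1.19 ± 0.25. Of 49 replication genes 12 fell, 13 down and 1 up when adjusted over the list alone (median -0.455, adjusted p = 0.153 with an estimated correlation), with the licensing factor CDT1 down by 1.10 ± 0.20. Cornified envelope genes had 10 of 47 raised in both counts, that over all genes and that adjusted over the list alone (median 0.327, adjusted p = 0.624 with an estimated correlation), with LCE4A up by 1.82 ± 0.34 and SPRR4 by 1.12 ± 0.25. The median of that list was -0.0154 with scaling to the median of each array. CALML5 rose by 1.06 ± 0.15 and the suprabasal keratin KRT2 by 1.20 ± 0.32. Inflammatory genes had 6 of 37 raised, 7 when adjusted over the list alone (median 0.504, adjusted p = 0.153 with an estimated correlation), with PTGS2 up by 2.03 ± 0.32 and the interleukin 1 antagonist IL1RN by 1.13 ± 0.24. PPP1R15A (NCBI gene 23645, chromosome 19), a phosphatase subunit of the integrated stress response, rose by 1.44 ± 0.14 (adjusted p = 2.18e-05).

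Respiratory chain genes encoded in the nucleus had 8 of 49 lowered at 24 h after 2.5 Gy, 12 when adjusted over the list alone (median -0.253, adjusted p = 0.539 with an estimated correlation), with NDUFAB1, a subunit of complex I, down by 0.785 ± 0.146. Histone genes had 5 raised and 2 lowered of 26, 9 and 2 when adjusted over the list alone (median 0.385, adjusted p = 0.695 with an estimated correlation). Of 26 basal genes 5 fell in both counts, that over all genes and that adjusted over the list alone (median -0.13, adjusted p = 0.539 with an estimated correlation), and the median was 0.0743 with slide as a fixed block. Homologous recombination and Fanconi anaemia genes had 8 of 35 lowered, 10 when adjusted over the list alone (median -0.326, adjusted p = 0.153 with an estimated correlation). Some markers of other cell types rose too: of 12 melanocyte markers 4 rose, 5 when adjusted over the list alone (median 0.518, adjusted p = 0.512 with an estimated correlation), with the pigment enzyme DCT up by 2.74 ± 0.61. Of 11 endothelial markers 2 rose, 3 when adjusted over the list alone (median 0.815, adjusted p = 0.652 with an estimated correlation). These medians were 0.176 and 0.0682 without the 2 arrays. GDF15 at -0.120 ± 0.282, CDKN1A at -0.244 ± 0.164, MDM2 at -0.390 ± 0.248, KRT14 at -0.332 ± 0.132, KRT10 at 0.0147 ± 0.154 and IVL at 0.403 ± 0.186 did not pass.

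In all 3212 genes changed at 24 h after 2.5 Gy, 1964 up and 1248 down, and the median of all genes was 0.0943. On 522 of them 1 group was not well above background on any array. Without the 2 arrays with more spots above background 3764 changed, of which 2649 were called in the same direction in both fits. In the fit with slide as a fixed block 14 genes changed and no mitosis gene passed (median -0.362, adjusted p = 0.0953 with an estimated correlation), and with both 658 changed and the mitosis median was -0.564. The share that rose was 61.1%, against 49% with quantile normalization and 46.3% in the deposited values.

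At 24 h after 10 cGy, 17 of 49 respiratory chain genes were lower, while 6 of 42 matrix genes and 4 of 37 inflammatory genes were higher, and none of these lists passed with an estimated correlation. Of 49 respiratory chain genes 17 fell, 30 when adjusted over the list alone (median -0.402, camera adjusted p = 2.52e-17, but adjusted p = 0.268 with an estimated correlation), with the complex I subunits NDUFAB1 down by 0.811 ± 0.146 and NDUFS8 by 0.821 ± 0.152. Matrix remodelling and wound response genes had 6 of 42 raised, 13 raised and 1 lowered when adjusted over the list alone (median 0.5, adjusted p = 0.268 with an estimated correlation), with SERPINB2 up by 1.30 ± 0.21 and epiregulin (EREG) by 1.25 ± 0.23. Inflammatory genes had 4 of 37 raised in both counts, that over all genes and that adjusted over the list alone (median 0.557, adjusted p = 0.268 with an estimated correlation), with PTGS2 up by 1.82 ± 0.32 and the cytokine IL1A by 0.760 ± 0.201. On the slide with the controls, through 1 irradiated array, the inflammatory median was 0.105 and the matrix median 0.371, against 0.623 and 0.52 for the 2 arrays on the other slide. Melanocyte, endothelial and leukocyte markers had medians of 0.742, 0.648 and 0.543 that did not pass (adjusted p = 0.108, 0.21 and 0.331), and of 0.13, 0 and 0 on the slide with the controls. Cornified envelope genes had 1 raised and 6 lowered of 47 and did not pass as a list (median 0.0235, adjusted p = 0.21). Among them loricrin (LORICRIN) fell by 1.75 ± 0.37 and filaggrin (FLG) by 0.920 ± 0.189. The basal keratins KRT5 and KRT14 fell by 0.603 ± 0.134 and 0.581 ± 0.132, and CDKN1A by 0.675 ± 0.164, none of which passed without the 2 arrays (KRT5 -0.485, adjusted p = 0.0666; KRT14 -0.441, adjusted p = 0.0758; CDKN1A -0.531, adjusted p = 0.104). Of 27 NRF2 targets 7 fell and 1 rose, 9 and 2 when adjusted over the list alone (median -0.116, adjusted p = 0.712 with an estimated correlation), with the aldo-keto reductase AKR1B10 down by 1.19 ± 0.14.

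Outside these lists at 24 h after 10 cGy, GFPT2 was at least 12.8-fold higher and the zinc finger gene ZNF114 (NCBI gene 163071, chromosome 19) at least 10.6-fold, both not well above background in the controls. HSD11B2 (NCBI gene 3291, chromosome 16), which inactivates cortisol, fell by 1.57 ± 0.15 (adjusted p = 7.87e-06) and the retinoic acid hydroxylase CYP26A1 by 2.12 ± 0.23, and these 4 genes passed with slide as a fixed block too. Mitosis genes did not pass as a list (median 0.205, 1 lowered, adjusted p = 0.237), and on the slide with the controls the median was 0.238. GDF15 at -0.704 ± 0.282, MDM2 at -0.455 ± 0.248, KRT10 at -0.254 ± 0.154 and IVL at 0.101 ± 0.186 did not pass. In all 2108 genes changed, 812 up and 1296 down, and the median of all genes was 0.128. Without the 2 arrays 760 changed, of which 629 were called in the same direction in both fits, and respiratory chain genes then had 5 lowered (median -0.254). In the slide block fit 46 changed and no respiratory chain gene passed (median -0.282), and with both 1240 changed. The share that rose was 38.5%, against 20.9% with scaling to the median and 66.9% with normexp, under which 6909 genes changed.

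Compared directly at 24 h, mitosis genes were lower after 2.5 Gy than after 10 cGy, while 4 of 26 histone, 3 of 47 cornified envelope and 1 of 29 barrier lipid genes were higher at the threshold over all genes, and these 3 lists did not pass with an estimated correlation. Of 54 mitosis and G2/M genes 7 were lower, 33 lower and 1 higher when adjusted over the list alone (median -0.733, camera adjusted p = 8.52e-26, and 0.0498 with an estimated correlation), with SGO1 at -1.70 ± 0.25 and BIRC5 at -1.04 ± 0.19. Histone genes had 4 of 26 higher, 18 higher and 1 lower when adjusted over the list alone (median 0.525, adjusted p = 0.117 with an estimated correlation). Cornified envelope genes had 3 of 47 higher, 13 when adjusted over the list alone (median 0.332, adjusted p = 0.117 with an estimated correlation), with RPTN at 2.27 ± 0.34 and FLG at 0.929 ± 0.189. Barrier lipid genes had 1 of 29 higher, the fatty acid elongase ELOVL1 at 0.992 ± 0.121, and 8 when adjusted over the list alone (median 0.32, adjusted p = 0.117 with an estimated correlation). CALML5 was higher by 1.36 ± 0.15 (adjusted p = 0.000115), the antioxidant enzyme GPX2 by 0.958 ± 0.148 and OASL, an interferon-stimulated gene, by 1.15 ± 0.17. In all 231 genes differed, 150 higher and 81 lower. A fit of only the 6 arrays compared gave 0 (1588 at an unadjusted p under 0.05). Of the 10 splits of these arrays into 3 and 3, 5 gave at least as many genes, the real one included. The highest gave 4186. The fixed slide block left 76 that differed, and with it the mitosis median was -0.585 with 5 genes lower (adjusted p = 0.00142 with an estimated correlation), and on the shared slide 1 of 54 mitosis genes was higher after 2.5 Gy. Without the 2 arrays 311 differed, the mitosis median was -0.814 (adjusted p = 0.177 with an estimated correlation), and FLG did not pass (0.774, adjusted p = 0.0883). The share higher after 2.5 Gy was 64.9%, against 50.7% with quantile normalization.

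**Figure D3:**
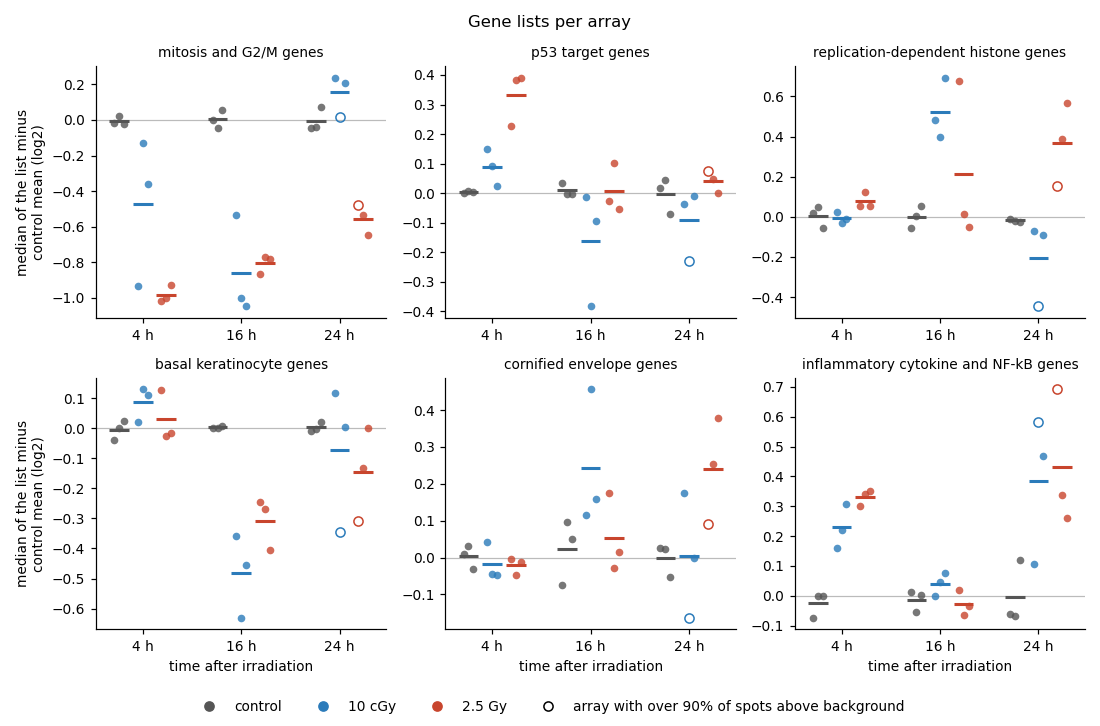
Median over each of 6 gene lists on each array, relative to the mean of the controls of that time (vertical axis, log2), by time after irradiation (horizontal axis), for control (grey), 10 cGy (blue) and 2.5 Gy (red), with bars at group means and open circles for the 2 arrays with over 90% of spots above background. Mitosis medians of all 2.5 Gy arrays lay below those of the controls at each time, while those of 10 cGy lay below them at 4 and 16 h and not at 24 h.

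The response to each dose was tested for a difference between times with an F test of the interaction, which found 1236 genes for 2.5 Gy and 1518 for 10 cGy. The effect of 2.5 Gy on S100A7A was higher by 4.25 at 16 h and by 6.01 at 24 h than at 4 h (adjusted p = 0.000727), and that on MMP3 was lower by -3.56 and -2.86 (adjusted p = 0.00102), with fitted values that rest on the floor. For IL15, a lymphocyte growth factor, the effect was higher by 1.36 and 2.3, and for PPP1R15A by 0.55 and 1.6. The effect of 10 cGy on OAS1 was higher by 1.06 at 16 h and lower by -0.797 at 24 h than at 4 h (adjusted p = 0.000146), and that on GPX2 was 0.972 and -0.832. Mitosis genes as a list had a 10 cGy effect that was higher at 24 h than at 16 h, with a median difference of 1.08 and 52 of 54 genes above 0 (camera adjusted p = 1.15e-13, but adjusted p = 0.26 with an estimated correlation). The p53 list had a 2.5 Gy effect lower at 16 h than at 4 h (median -0.351, adjusted p = 9.89e-07, but adjusted p = 0.144 with an estimated correlation). With slide as a fixed block 25 genes passed for 2.5 Gy and 112 for 10 cGy, and without the 2 arrays 2230 and 1647. Unirradiated controls at 4 h themselves differed from those at 16 h in 10936 genes, and 4 h arrays had their own slides and scan day. A response that differs from that at 4 h therefore cannot be told from one that differs with the state of the tissues, slide or scan day.

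In the unirradiated controls 12252 genes differed between the times. The keratin KRT2 was lower by -9.76 at 16 h and -9.49 at 24 h than at 4 h (adjusted p = 1.53e-14), and CYP26A1, induced by retinoic acid, was higher by 5.76 and 4.69. The lipid carrier APOE was higher by 3.21 and 3.26, and PTPN21, a tyrosine phosphatase, was lower by -4.1 and -4.21. Of 29 barrier lipid genes 20 were lower and 2 higher at 16 h, 21 and 2 when adjusted over the list alone (median -1.14, adjusted p = 0.0673 with an estimated correlation). Matrix remodelling and wound response genes had 27 of 42 higher and 3 lower, 29 and 4 when adjusted over the list alone (median 0.983, adjusted p = 0.0673 with an estimated correlation). Metallothionein genes, which bind metals, had 11 of 13 higher and 2 lower in both counts (median 2.2, adjusted p = 0.431 with an estimated correlation). Between 16 and 24 h 1753 genes changed, between 4 and 16 h 10936, and between 4 and 24 h 10776. Controls of each time shared 1 slide and the 4 h arrays were scanned on another day, so these differences hold time, slide and scan day together, and a fit with slide as a block gives no value.

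**Figure D4:**
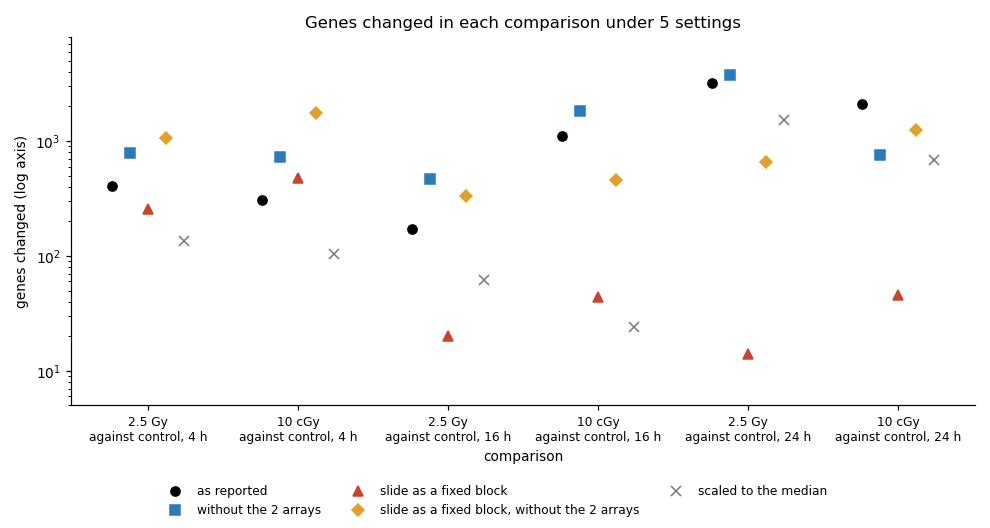
Genes changed (vertical axis, log scale) in each of 6 comparisons of a dose with its control (horizontal axis), as reported, without the 2 arrays, with slide as a fixed block, with both, and scaled to the median. At 24 h after 2.5 Gy the counts were 3212, 3764, 14, 658 and 1532 in that order.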

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

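The F tests of the interaction of dose with time were planned, and the splits and the tests of explanations in this part, on the spike-ins, slides, scaling, basal genes and control times, were chosen only after the results were seen.

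The response to 2.5 Gy differed between times in 1236 genes and that to 10 cGy in 1518, by F tests of the interaction itself. In 100 splits drawn with a fixed seed, the real one included, no other split gave as many, with highest values of 551 and 588. The splits moved dose labels within each time, so they set the counts against no effect of dose at any time. They cannot decide whether an equal effect at all times would give such counts, and slides run largely with dose. Nor do they part time from the slides and scan day of 4 h, or from the state of the tissues, which differed between control times. For the 2 doses 25 and 112 genes passed with slide as a fixed block, and without the 2 arrays 2230 and 1647. As a list, mitosis and G2/M genes had an effect of 10 cGy that was higher at 24 h than at 16 h by a median of 1.08, with 52 of 54 genes above 0, 20 higher and 1 lower over all genes, and 31 and 1 when adjusted over the list alone. Fry gave an adjusted p of 0.000935, and camera 1.15e-13 at its preset correlation and 0.26 with an estimated one. Without the 2 arrays the median was 0.966.

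On the 2 arrays at 24 h with more spots above background, spike-ins, which the comparisons do not use, stood outside the range of the other arrays at 16 and 24 h. The weakest of 10 spike-ins had a signal of 134.6 on the lower of the 2, where the others spanned 6.86 to 22.7. Another weak one had 66.79 on the lower of the 2, against 21.6 to 48.8.

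The higher share of spots above background on these 2 arrays was weighed against 3 explanations. Against a brighter scan of the whole array, the weakest spike-in was 11-fold above its median on the other arrays at 16 and 24 h, while the strongest was 1.03-fold. For a raised background under every spot, negative controls had a median of -7.15 on the 2 arrays, within the range of -18.6 to -3.25 on the others. These values were taken after background subtraction, which would remove such a background, so they cannot decide on it. Against a difference between the cultures alone, 3 of the 10 spike-ins, which no tissue contains, were above the range of the other arrays at 16 and 24 h on both arrays. The other 2 arrays of the slide had 68.2% and 69.4% of spots above background, so a candidate explanation left open is a step that reached only these 2, and a difference between the cultures beside it was not tested.

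Lower mitosis and G2/M genes after irradiation were weighed against slides, scaling and a loss of basal cells. Among quantile normalization, scaling to the median and normexp, the smallest fall for 2.5 Gy at 4 h was -0.701, with normexp. Normexp changed the background correction and not the scaling, and the fall was no smaller under the other settings. Against slides as the whole cause for 2.5 Gy at 4 h, the list was lower after 2.5 Gy than after 10 cGy within the slide that held 2 arrays of each (-0.751, adjusted p = 0.000202 with an estimated correlation). For 2.5 Gy at 16 h (0.164 against 10 cGy within that slide) and for 10 cGy at 4 h and 16 h (-0.933 and -0.535 with slide as a fixed block, but resting on 1 irradiated array, where the other 2 had -0.258 and -0.934), slide and dose cannot be told apart. Basal keratinocyte genes had a median of 0.0342 for 2.5 Gy at 4 h (quartiles -0.128 to 0.213, against -1.21 to -0.75 for mitosis genes), which argues against a loss of basal cells there, while at 16 h medians of -0.274 after 2.5 Gy and -0.556 after 10 cGy, with quartiles that overlap those of the mitosis genes, leave fewer basal cells open. An effect of the dose on cycling cells stays a hypothesis, since it was found and tested on the same arrays.

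The large differences between the controls at 4 h and those at 16 and 24 h were weighed against labelling, hybridization, slide and scanning, which the spike-ins share with the genes. Over the 9 spike-ins above the floor on all 9 controls, differences from 4 h (log2) ran from -1.19 to -0.196 at 16 h. At 24 h they ran from -1.35 to 0.102. Most thus lay below 0, a shift whose cause was not tested, and the counts of genes that differed between control times make no allowance for it. The SD of these differences was 0.33 at 16 h and 0.461 at 24 h. Each of 18214 genes above the floor was set against that SD in a t test, adjusted by Benjamini-Hochberg over these genes. With the median gene as the centre, 868 passed the same way at both later times (t test adjusted p under 0.05 at each). With the mean of the spike-ins as the centre 5313 did, so this choice moves the count several-fold. The same way with both were 620, with differences of at least 1.33, among them KRT2 at -9.76 and PTPN21 at -4.1. This argues against those steps as the whole cause for these 620 genes, if probes vary in them as the 9 spike-ins do. For the other genes time and these steps cannot be told apart, and time in culture and the batch of tissues stay open for all.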

How the results depend on the processing

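Tests added only after the arrays were seen were slide as a fixed block, leaving out the 2 arrays, both together, the floor of 0.01 and the spots held before normexp; the other settings were planned. In what follows, counts are genes at an adjusted p under 0.05 by limma unless stated, counts not printed stayed within 1.5 times those of the report except between the ends of the ranges for 1 array left out, and the cause of each difference was not tested unless one is given. As reported, the counts against control were 406 and 307 at 4 h, 173 and 1109 at 16 h and 3212 and 2108 at 24 h, with 2.5 Gy first in each pair. The doses differed in 2, 57 and 231 genes at 4, 16 and 24 h, the response to 2.5 Gy and to 10 cGy differed between times in 1236 and 1518, and the controls differed in 12252.

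With no filter on dim probes all 12 counts stayed within 1.5 times. With a floor of 0.01, 11 did, and the doses differed in 6 genes at 4 h. The mean of a gene's probes gave 1 and 27 genes between the doses at 4 and 16 h, a replicate block gave 1 and 29, and the deposited log2 values gave 6 and 112. Quantile normalization gave 18 genes between the doses at 4 h and 761 at 24 h. An intensity trend gave 267 genes for 2.5 Gy at 16 h, and 7, 172 and 375 between the doses at 4, 16 and 24 h. Normexp gave 102 genes for 2.5 Gy at 16 h, 6909 for 10 cGy at 24 h, and 8 and 36 between the doses at 4 and 16 h. It was run with 56 spots on 9 arrays held, because with none held it gave 2 genes for 2.5 Gy at 4 h and 17293 for 10 cGy at 4 h.

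Scaling to the median of each array gave 135 and 104 genes against control at 4 h, 62 and 24 at 16 h, and 1532 and 685 at 24 h, with 2.5 Gy first in each pair. Between the doses it gave 1, 0 and 20 at 4, 16 and 24 h, and the interactions with time had 325 and 66. Beside its 0 at 16 h, limma gave 1493 genes at an unadjusted p under 0.05. A filter on all 27 arrays gave 539 genes for 10 cGy at 4 h, 286 and 1800 for the doses at 16 h, 9, 285 and 592 between the doses, and 2522 for the interaction of 10 cGy with time. At an unadjusted p under 0.001 there were 340 genes for 2.5 Gy at 16 h, 1520 and 1060 for the doses at 24 h, 87, 264 and 381 between the doses, 766 and 881 for the interactions and 7790 in the controls. These counts rest on another threshold, not on other values.

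A fit of only the groups compared, with 6 arrays each, gave 1491 and 497 genes at 4 h, 215 for 10 cGy at 16 h, 2 for 10 cGy at 24 h, and 9, 0 and 0 between the doses. For these counts of 0 at 16 and 24 h limma gave 1772 and 1588 genes at an unadjusted p under 0.05. Array weights gave 4064 and 5461 genes at 4 h, 2018 and 2595 at 16 h, 12122 and 3547 at 24 h, 1495, 624 and 1768 between the doses, 10724 and 6158 for the interactions and 18741 in the controls. They gave the 2 arrays with more spots above background weights of 0.0978 and 0.152, where the lowest of the others was 0.251. Without the 2 arrays there were 792 and 719 genes at 4 h, 471 and 1826 at 16 h, 760 for 10 cGy at 24 h, 13 and 257 between the doses at 4 and 16 h, and 2230 for the interaction of 2.5 Gy. At 4 and 16 h no array compared was left out, so these counts differ through the shared spread alone.

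Slide as a random block, with a correlation of 0.114 within slides, gave 228 genes for 2.5 Gy at 4 h, 52 and 642 at 16 h, 1405 and 1211 at 24 h, 4 and 91 between the doses at 4 and 16 h, and 107 and 788 for the interactions. Slide as a fixed block gave 256 and 472 genes at 4 h, 20 and 44 at 16 h, 14 and 46 at 24 h, 29, 139 and 76 between the doses, and 25 and 112 for the interactions. For the controls over time it could not be fitted, since their slides and times coincide. The fixed block without the 2 arrays gave 1071 and 1736 genes at 4 h, 330 and 462 at 16 h, 658 and 1240 at 24 h, and 212, 1040 and 394 between the doses. The fixed block leaves few arrays to carry each comparison with control, which lowers its precision by construction.

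Of the 79 gene list shifts that passed and were not very small, 6 changed sign under some setting. Lists that passed with a very small median were not followed. The basal keratinocyte median for 2.5 Gy at 24 h was 0.0743 with slide as a fixed block, in place of -0.13, and under it the matrix remodelling median for 2.5 Gy at 4 h was -0.0119 in place of 0.16, with the 2 arrays and without them. Quantile normalization gave a cholesterol synthesis median of 0.0394 for 10 cGy at 24 h in place of -0.236. Scaling to the median gave a cornified envelope median of -0.0154 for 2.5 Gy at 24 h in place of 0.327. Leaving out 10 cGy replicate 1 at 4 h gave a homologous recombination and Fanconi anaemia median of 0.0163 in place of -0.165 (the range over the 6 arrays was -0.265 to 0.0163), and leaving out 2.5 Gy replicate 1 at 16 h gave a histone median of -0.00256 in place of 0.207 (range -0.00256 to 0.354). For these too the cause was not tested. No gene named by the rule changed sign with a call. Over the settings other than leaving out 1 array, 3647 values kept their side of the threshold, 850 no longer passed and 32 newly passed. The direction of values that passed in neither fit was not followed. Of the 79 list calls followed, made by camera at its preset correlation, 10 held with an estimated correlation and 46 with fry.

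Leaving out 1 array at a time gave ranges that name the array left out at each end. For 2.5 Gy at 4 h the counts ran from 129 (2.5 Gy replicate 2) to 200 (2.5 Gy replicate 3), and for 10 cGy from 107 (10 cGy replicate 3) to 229 (10 cGy replicate 1). At 16 h they ran from 49 (control replicate 3) to 441 (2.5 Gy replicate 1) for 2.5 Gy, and from 235 (10 cGy replicate 2) to 1977 (10 cGy replicate 1) for 10 cGy. At 24 h they ran from 1315 (control replicate 1) to 2579 (control replicate 3) for 2.5 Gy, with 1583 without control replicate 2 and 2094 and 2133 without 2.5 Gy replicates 2 and 3. For 10 cGy at 24 h they ran from 419 (control replicate 1) to 3982 (10 cGy replicate 1), with 464 without control replicate 2 and 537 without 10 cGy replicate 2. Between the doses the ranges were 1 (10 cGy replicate 2) to 45 (10 cGy replicate 1) at 4 h, 11 (10 cGy replicate 2) to 570 (2.5 Gy replicate 1) at 16 h, and 99 (2.5 Gy replicate 2) to 744 (10 cGy replicate 3) at 24 h. For the interactions they were 252 (control replicate 1 at 24 h) to 1920 (2.5 Gy replicate 3 at 16 h) and 537 (control replicate 1 at 24 h) to 2851 (10 cGy replicate 1 at 24 h), and for the controls over time 10705 to 11554. The count moved by over 1.5 times for each of the 6 arrays for 2.5 Gy at 4 and 16 h, 10 cGy at 16 h and between the doses at 4 h, for 5 of 6 for 10 cGy at 4 h and between the doses at 16 h, for 4 of 6 in the 3 comparisons at 24 h, for 13 and 9 of 18 for the interactions, and for 0 of 9 for the controls. A group left with 2 arrays shares the spread of the others, and fewer arrays by themselves lower a count.

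Among changed genes with several probes, 28 of 95 for 2.5 Gy and 24 of 84 for 10 cGy at 4 h, 13 of 45 and 93 of 378 at 16 h, and 292 of 840 and 196 of 617 at 24 h had probes of both signs. No pairing of the samples by replicate number was seen across the comparisons, where 0 to 4 of the 6 arrays correlated best with the array of their own number. The count was 4 for 10 cGy against control at 16 h, and so few arrays cannot exclude a pairing. Signal over background limits what can be said of dim genes: where a group was not well above background on any array, as in 48 of the 406 genes changed for 2.5 Gy at 4 h and 522 of 3212 at 24 h, the fold rests on the floor and is a lower bound.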

Other observations

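The lists were planned, while the tests by splits, the overlap of the 2 doses and the retinoid test were chosen only after results had been seen.

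Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. For 2.5 Gy against control the real split gave 406 genes at 4 h, 173 at 16 h and 3212 at 24 h, and the highest other split gave 2, 7 and 20. For 10 cGy against control the real values were 307, 1109 and 2108 and the highest others 34, 3 and 8. In each of these 6 comparisons the number of splits with as many genes was 1, the real one. The 3 controls of a time share a slide that holds only 1 irradiated array, so the real split is nearly a split by slide. These counts therefore do not part dose from slide. Between the doses the real values were 2, 57 and 231 and the highest others 2, 131 and 4186, with 2 splits as large at 4 h, 2 at 16 h and 5 at 24 h. The split with 131 genes at 16 h put 2.5 Gy replicate 1 with 10 cGy replicates 2 and 3, which are 3 of the 4 arrays of one slide, and with slide as a fixed block the doses differed in 139 genes. At 24 h the 4 splits that put the 2 arrays with more spots above background on one side gave 1891, 2059, 4186 and 1865 genes, which points to a structure of the samples, and without these arrays the doses differed in 311. For time in the controls 1 of 100 seeded splits, the real one, gave 12252 genes and the highest other 9709. This argues against a chance division of the arrays. It does not part time from slide, since the controls of each time share 1 slide.

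Both doses were compared with the same 3 controls, which alone makes their fold changes correlate. At 4 h 85 genes rose after both doses, against 1.21 for independent sets of the same sizes, and 76 fell, against 1.16. At 16 h 17 rose and 90 fell, against 0.415 and 4.25, and at 24 h 445 rose and 475 fell, against 60.8 and 61.7, with 2 genes opposite. Across genes the 2 sets of fold changes correlated at 0.685, 0.573 and 0.736 at 4, 16 and 24 h, and at 0.501, 0.5 and 0.501 in data simulated with shared controls and no effect. The controls of a time were then divided, 1 to one dose and 2 to the other, in each of 6 ways, with the lone control assumed to vary like the other groups. The correlations, which no control is then shared to raise, ran from 0.3 to 0.45 at 4 h, 0.21 to 0.294 at 16 h and 0.521 to 0.683 at 24 h. Genes that rose after both doses numbered 2 to 16, 1 to 5 and 6 to 22, and those that fell 3 to 11, 16 to 28 and 3 to 30, each above its value for independent sets (at most 2.3 and 6.27). All controls of a time still share a slide, which division does not undo. At each time 2 arrays of each dose also share another slide, which can raise the agreement of the doses. At 24 h each dose holds 1 of the 2 arrays with more spots above background, and the overlap and correlations were not computed without these arrays.

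Several lists had changed members without passing as a list by camera. Hypoxia and glycolysis genes had 6 raised and 1 lowered of 35 at 24 h after 10 cGy (median 0.0432, adjusted p = 0.966), with ANKRD37 up by 1.32 ± 0.21 and the hexokinase HK2 by 0.771 ± 0.195. Of 45 interferon-stimulated genes 5 fell there (median 0.00592, adjusted p = 0.21), with HERC6 down by 1.19 ± 0.16. Of 20 heat shock genes 2 rose and 5 fell at 16 h after 10 cGy (median -0.169, adjusted p = 0.189), with the collagen chaperone SERPINH1 down by 1.14 ± 0.24. Among clock genes the nuclear receptor NR1D2 rose at 4 h by 1.59 ± 0.26 after 2.5 Gy and by 1.34 ± 0.26 after 10 cGy, and at 24 h by 1.02 ± 0.26 and 1.13 ± 0.26, while the list had adjusted p-values of 0.61, 0.677, 0.445 and 0.43. Integrated stress and unfolded protein response genes had 1 of 30 raised at 24 h after 10 cGy (median 0.132, adjusted p = 0.47), and activated keratinocyte genes had 2 raised and 2 lowered of 25 at 4 h after 2.5 Gy (median -0.0912, adjusted p = 0.239).

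Other lists passed by camera at its preset correlation and not with an estimated one. Of 24 cholesterol synthesis genes 3 fell and 1 rose at 24 h after 10 cGy, 7 and 1 when adjusted over the list alone (median -0.236, adjusted p = 0.0237, but adjusted p = 0.713 with an estimated correlation), and with quantile normalization the median was 0.0394. Of 13 metallothionein genes none passed over all genes and 4 were lower when adjusted over the list alone between 2.5 Gy and 10 cGy at 4 h (median -0.557, adjusted p = 3.58e-07, but adjusted p = 0.19 with an estimated correlation). NRF2 targets had 1 of 27 lowered at 4 h after 2.5 Gy (median -0.222, adjusted p = 0.000245, but adjusted p = 0.177 with an estimated correlation). Leukocyte and Langerhans cell markers had a median of 0.272 at 16 h after 10 cGy (adjusted p = 0.026, but adjusted p = 0.489 with an estimated correlation), and at 24 h after 2.5 Gy 4 of 19 rose (median 0.409, adjusted p = 0.223). Fibroblast markers had 2 of 16 raised and 1 lowered there (median 0.0167, adjusted p = 0.642), and none of 8 Merkel and nerve cell markers passed (median 0.32, adjusted p = 0.794).

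Retinoid signalling was tested as a hypothesis for the higher CYP26A1 and KRT13 and the lower KRT2 and LORICRIN in the later controls. Of 11 other retinoid-responsive genes 8 were higher at 16 h than at 4 h, with a median of 1.03. LRAT was higher by 4.19, STRA6 by 2.36, TGM2 by 1.76 and CRABP2 by 1.38, while CYP26B1 and DHRS3 had values of -1.6 and -0.667. Members that move both ways leave the hypothesis open, and slide and scan day run with time in these controls.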
